A study of Mus musculus with 32 samples.

How the data were processed

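The series measured mouse B cells with 32 samples, of which 21 are RNA libraries and 11 are chromatin immunoprecipitation or input samples, which were not analysed here. Per the labels' protocols, B cells were purified from C57Bl/6 mice, cultured with 15 µg/mL LPS with or without 250 nM JQ1 and harvested at 2, 8 or 48 h. Total RNA was extracted with a Qiagen RNeasy kit with removal of genomic DNA, and libraries were made from 100 ng with the Lexogen QuantSeq 3' mRNA kit and sequenced on an Illumina NextSeq 500, per the labels' protocols. Such a kit places reads near the 3' end of polyadenylated transcripts, so a gene's count does not scale with its length, and isoforms that share a 3' end are not told apart.

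The authors deposited a table of counts, with whole numbers of reads per gene for 51912 Ensembl genes in 21 columns. The submitters' processing notes name cutadapt 1.9, HISAT2, featureCounts, limma, CASAVA 1.8.2, Bowtie2 2.2.3, SAMtools 1.3 and deepTools 2.0 and the genome build mm10, without saying which served the RNA libraries. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical genes may therefore be split or lost, and overlapping or antisense genes cannot be told apart. Values of genes in multigene families are uncertain throughout, also where this is not repeated. Such families include the histone, Bcl2a1, ribosomal protein and immunoglobulin genes. Each of the 21 columns matched the label of 1 sample, and 0 columns were left unmapped. Of the rows, 51633 (99.5%) were given a gene symbol from a table of Ensembl identifiers. Coordinates are those of RefSeq genes on GRCm38.

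Samples were grouped by time and treatment from their labels, which gave 7 groups of 3. No pair of libraries within a group held identical values, and each library was counted as a sample. The chi-square per degree of freedom between replicates lay between 2.42 and 273. The highest values, 212 and 273, both involve untreated 48 h replicate 1. These values do not tell separate cultures from technical repeats. Totals per library ran from 4374423 to 24437649 counts, and the mitochondrially encoded rows held 0 counts in all libraries. A count of 0 allows a level of up to 0.839 CPM in the library of the smallest TMM-adjusted size, taken as 3 counts and covering counting error only.

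The counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 13904 genes, libraries were scaled with TMM factors, and a quasi-likelihood model with robust dispersion was fitted to all 21 libraries with a mean per group, so that the groups share an estimate of spread. The biological coefficient of variation was 11.1%. The contrasts, tested two-sided, were 2, 8 and 48 h against 0 h without JQ1, JQ1 against untreated at 2, 8 and 48 h, and the differences of the JQ1 effect between times. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Standard errors of log2 fold changes come from the same model, and CPM in the text are counts scaled to a common TMM-adjusted library size.

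For JQ1 and for LPS, the genes named were picked by a rule fixed in advance: 21 anchor genes, the genes with the largest changes each way (8 for JQ1, 5 for LPS and for the differences) among those past the threshold with a mean of at least 10 CPM and no overlap between the groups, and up to 4 (JQ1) or 3 (LPS) members of each list by adjusted p. Predicted genes, pseudogenes and immunoglobulin variable segments were left out of the ranking, and no overlap rule applied to the differences. The 27 lists, of 534 genes, cover BET inhibitor response markers, BET proteins and P-TEFb, the Myc network, ribosome biogenesis, G1/S, G2/M, CDK inhibitors, pro-survival and pro-apoptotic genes, NF-kB, immediate early, interferon-stimulated, activation, B cell identity, plasma cell, unfolded protein response, class switch, glycolysis, cholesterol, lysosome and p53 genes, markers of T, myeloid, dendritic and NK, erythroid and marginal zone or B1 cells, and mitochondrially encoded transcripts. They were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry.

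The scripts were tested on simulated data drawn from the means and sizes of these libraries. Of simulated 2-fold changes, 71.6%, 62.7% and 65.7% were called in comparisons like those with JQ1 at 2, 8 and 48 h (13682 genes), and 64.2%, 67.2% and 79.1% in those like LPS at 2, 8 and 48 h (12946 genes). Of the simulated calls 3.76%, 9.42% and 11.5% were false for JQ1, and 7.35%, 2.36% and 6.25% for LPS. In each of these comparisons 67 genes were changed by 1.5 times, 67 by 2 times and 66 by 4 times. The real comparisons called far more genes, so these false shares do not carry over to the real counts. Alternatives were DESeq2 1.42.0 with its Wald test, limma-voom, other scaling factors (median-of-ratios, upper-quartile, library totals), no or a stricter low-count filter (5 CPM in 3 libraries), a fit of the groups compared alone, a replicate block, each library left out in turn, and, added after the data were seen, Gm42418 left out, the same with all libraries thinned to equal depth, and rows nearly identical to another (within 0.2 on the log2 scale at a mean count of at least 20) left out.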

Results

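Follicular B cells purified from C57Bl/6 mice were cultured with lipopolysaccharide (LPS, 15 µg/mL), a bacterial cell wall component that activates B cells through a Toll-like receptor, and either received the drug JQ1 (250 nM) or did not. JQ1 is a small molecule that displaces BET bromodomain proteins, among them Brd4, from acetylated histones. The 3' ends of mRNA were sequenced in 21 libraries, 3 in each of 7 groups: cells at 0 h, cells with LPS alone at 2, 8 and 48 h (called untreated) and cells with LPS and JQ1 at 2, 8 and 48 h. The title of the study names survival, proliferation and differentiation of B cells. The comparisons below ask which transcripts changed from 0 h in culture with LPS and which differed with JQ1 at each time. Library totals were 13024379 to 24437649 counts in the untreated 48 h group, 4374423 to 5159609 in the JQ1 48 h group and 5507403 to 10192058 in the other groups. The most abundant row was Gm42418, an annotated non-coding gene that overlaps ribosomal RNA sequence, with 28.2 ± 3.33% of counts at 0 h, 14.1 ± 9.85% in the untreated 48 h group and 45.4 ± 3.25% in the JQ1 48 h group (mean ± SD, n = 3). In the remaining groups its mean share lay between 30.2% and 37.1%. The first principal component held 40.6% of the variance and separated the untreated 48 h libraries from all others, and the next held 16.8%. Of 51912 rows, 13904 genes passed the filter on low counts and were tested.

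**Figure D1:**
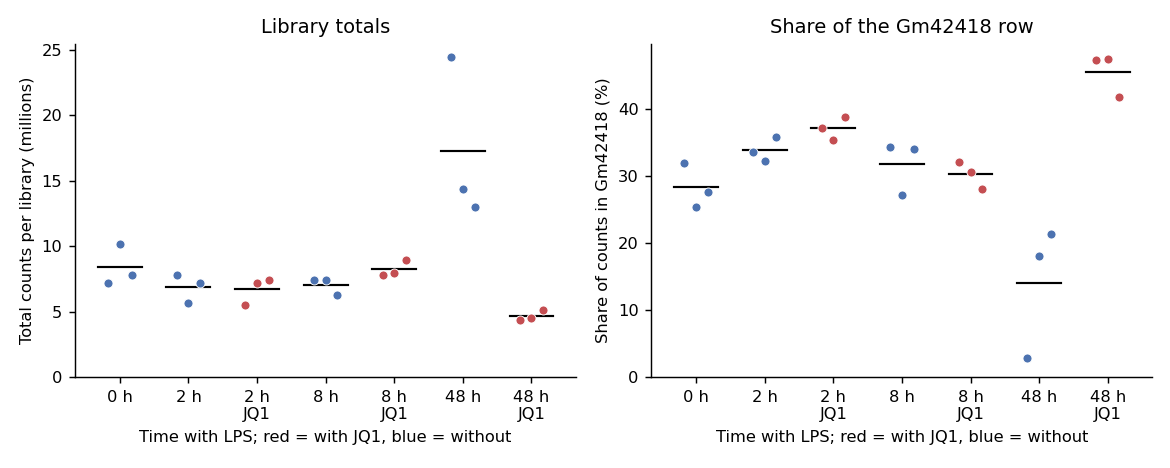
Total counts (left, axis scaled as labelled) and share of counts in the Gm42418 row (right, percent) for each of the 21 libraries by group, where points are libraries, lines are group means, blue is without JQ1 and red is with JQ1. The untreated 48 h libraries held the most counts and the JQ1 48 h libraries the fewest, and the Gm42418 share was 2.89% to 21.4% in the former and 41.7% to 47.4% in the latter.

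Levels below are counts scaled to a common library size (CPM) as mean ± SD of the 3 libraries of a group, changes are log2 fold changes ± SE, and "rose" or "fell" is used of genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for the genes named. For each list the count of members that passed over all genes tested is given, and the count adjusted over the list alone follows where it differs, so that a list without that second count had the same count adjusted over the list alone. A list is called by camera, which compares its members with the other genes, and its adjusted p is followed by that obtained with an estimated correlation between members. The labels do not say whether the 3 libraries of a group came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. No spike-in was named, so every change is relative to the scaling between libraries.

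Within 2 h of LPS, NF-kB, immediate early, ribosome biogenesis and pro-survival genes rose from the 0 h level. Il2ra, which encodes the alpha chain of the interleukin 2 receptor, rose from 1.58 ± 0.421 to 92.1 ± 4.98 CPM (5.90 ± 0.28), Myc, a transcription factor that drives growth, from 3.56 ± 0.235 to 103 ± 23.6 CPM (4.85 ± 0.25), and Bcl2l1, the gene of the survival protein Bcl-xL, from 3.14 ± 0.941 to 73.4 ± 4.95 CPM (4.57 ± 0.20). The transcription factor gene Irf4 (3.28 ± 0.11), the cyclin gene Ccnd2 (3.38 ± 0.27) and the costimulatory receptor gene Cd86 (2.92 ± 0.13) also rose, whereas Bcl2 (-1.89 ± 0.11) fell. In the NF-kB list 22 of 26 measured members rose, 1 fell and 3 did not pass, or 23 and 1 adjusted over the list alone, with Nfkbiz at 4.22 ± 0.13 and Cd83 at 3.88 ± 0.13. Over the NF-kB list camera gave an adjusted p of 1.73e-34, and adjusted p = 3.38e-05 with an estimated correlation. Among immediate early genes, which respond to stimuli without new protein synthesis, 20 of 22 measured members rose, 1 fell and 1 did not pass, with Nr4a3 at 6.26 ± 0.23 and Egr1 at 4.38 ± 0.16. Camera gave the immediate early list adjusted p = 2.76e-23, and adjusted p = 0.000475 with an estimated correlation. In the ribosome biogenesis list 30 of 30 measured members rose, 0 fell and 0 did not pass (Gnl3 2.48 ± 0.10, Ncl 1.81 ± 0.10). As a list, ribosome biogenesis genes gave camera adjusted p = 1.78e-29, and adjusted p = 0.0208 with an estimated correlation. In the pro-survival list 8 of 11 measured members rose, 1 fell and 2 did not pass. This list counts Bcl2a1a, Bcl2a1b and Bcl2a1d as separate members here and below, and reads may be shared between them. For the pro-survival list the camera adjusted p was 7.38e-09, and adjusted p = 0.000505 with an estimated correlation. Activation and costimulation genes were mixed: 11 of 20 measured members rose, 7 fell and 2 did not pass, a call lost in limma (adjusted p = 0.0851, range over all alternatives 1.43e-05 to 0.0851). Over the activation list camera gave an adjusted p of 0.00135, and adjusted p = 0.00849 with an estimated correlation. The interferon-stimulated genes moved the other way: 22 of 27 measured members fell, 0 rose and 5 did not pass, with Stat1 at -2.03 ± 0.092 and Stat2 at -2.05 ± 0.14. Camera gave the interferon-stimulated list adjusted p = 1.55e-11, and adjusted p = 3.38e-05 with an estimated correlation. In the B cell identity list 19 of 30 measured members fell, 5 rose and 6 did not pass, with lower values for Cd22 (-2.10 ± 0.11), Cr2 (-1.63 ± 0.10) and Klf2 (-1.61 ± 0.12). As a list, B cell identity genes gave camera adjusted p = 9.52e-05, and adjusted p = 0.263 with an estimated correlation. In all, 3488 genes rose and 3611 fell between 0 and 2 h. With library totals in place of composition factors 66.3% of the calls were lower, against 50.9%. The 0 h group has no counterpart cultured without LPS, so effects of LPS and of culture cannot be separated here, and the sample labels also describe the 0 h libraries as LPS-stimulated.

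At 8 h p53 target, ribosome biogenesis and cholesterol synthesis genes stood above 0 h. Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 1.59 ± 0.682 to 52.1 ± 4.28 CPM (5.07 ± 0.23), and Bbc3, a pro-apoptotic target of p53, rose by 5.49 ± 0.17 on the log2 scale. In the p53 target list 17 of 19 measured members rose, 1 fell and 1 did not pass. For the p53 target list the camera adjusted p was 7.49e-19, and adjusted p = 0.000209 with an estimated correlation. In the cholesterol synthesis list 20 of 21 measured members rose, 0 fell and 1 did not pass, with Sqle at 2.66 ± 0.13 and Hmgcs1, an early enzyme of the pathway, at 2.24 ± 0.11. Over the cholesterol synthesis list camera gave an adjusted p of 3.59e-16, and adjusted p = 0.00453 with an estimated correlation. Ribosome biogenesis genes were above 0 h too: 30 of 30 measured members rose, 0 fell and 0 did not pass. Camera gave the ribosome biogenesis list adjusted p = 7.3e-35, and adjusted p = 0.00978 with an estimated correlation. For the NF-kB list 21 of 26 measured members rose, 1 fell and 4 did not pass, or 22 and 1 adjusted over the list alone (Traf1 2.80 ± 0.14). As a list, NF-kB genes gave camera adjusted p = 8.17e-12, and adjusted p = 0.00453 with an estimated correlation. For pro-survival genes 7 of 11 measured members rose, 2 fell and 2 did not pass (Bcl2l1 4.52 ± 0.20). For the pro-survival list the camera adjusted p was 5.23e-06, and adjusted p = 0.00453 with an estimated correlation. Lower than at 0 h were the interferon-stimulated genes, where 19 of 27 measured members fell, 4 rose and 4 did not pass (Cmpk2 -4.53 ± 0.34). Over the interferon-stimulated list camera gave an adjusted p of 9.81e-06, and adjusted p = 0.00153 with an estimated correlation. B cell identity genes were lower too: 21 of 30 measured members fell, 4 rose and 5 did not pass (Klf2 -2.67 ± 0.12, Ciita -2.33 ± 0.13). Camera gave the B cell identity list adjusted p = 2.58e-07, and adjusted p = 0.109 with an estimated correlation. Pro-apoptotic genes, of which Bbc3, Bax, Pmaip1 and Fas are also in the p53 target list, were above 0 h. Of these genes 7 of 14 measured members rose, 4 fell and 3 did not pass, or 8 and 4 adjusted over the list alone. The call was lost in limma (adjusted p = 0.0688, range over all alternatives 0.000811 to 0.0688). As a list, pro-apoptotic genes gave camera adjusted p = 0.00197, and adjusted p = 0.00978 with an estimated correlation. Myc was still higher than at 0 h (2.79 ± 0.26), at 24.7 ± 2.33 CPM, while Bach2, a repressor of plasma cell fate, fell by 1.45 ± 0.096 on the log2 scale. In all, 3606 genes rose and 3555 fell between 0 and 8 h.

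By 48 h the cell division lists had risen. Ccna2, the gene of cyclin A, rose from 0.985 ± 0.245 to 52.8 ± 4.97 CPM (5.75 ± 0.24) and the checkpoint kinase gene Bub1 by 5.86 ± 0.33 on the log2 scale. For the G2/M and mitosis list 25 of 25 measured members rose, 0 fell and 0 did not pass (median log2 fold change 4.79). For the G2/M list the camera adjusted p was 7.7e-26, and adjusted p = 0.0205 with an estimated correlation. For the G1/S and DNA replication list 30 of 30 measured members rose, 0 fell and 0 did not pass (Mcm6 3.33 ± 0.13, Pcna 2.89 ± 0.11). Over the G1/S list camera gave an adjusted p of 5.83e-25, and adjusted p = 0.0205 with an estimated correlation. Ribosome biogenesis genes stayed above 0 h: 30 of 30 measured members rose, 0 fell and 0 did not pass. Camera gave the ribosome biogenesis list adjusted p = 2.49e-22, and adjusted p = 0.0584 with an estimated correlation. Of the glycolysis and amino acid uptake list 18 of 22 measured members rose, 2 fell and 2 did not pass. As a list, glycolysis and amino acid uptake genes gave camera adjusted p = 7.72e-08, and adjusted p = 0.0779 with an estimated correlation. Of the cholesterol synthesis list 20 of 21 measured members rose, 0 fell and 1 did not pass. For the cholesterol synthesis list the camera adjusted p was 1.74e-06, and adjusted p = 0.0669 with an estimated correlation. Single genes of differentiation and class switching also rose: Prdm1, which encodes the plasma cell regulator Blimp-1, from 2.38 ± 0.408 to 40.2 ± 3.16 CPM (4.10 ± 0.21), Xbp1 by 0.78 ± 0.13 and Aicda, the deaminase of antibody class switching, by 2.69 ± 0.33 on the log2 scale. The plasma cell differentiation list was not called: 13 of 21 measured members rose, 5 fell and 3 did not pass. Over the plasma cell list camera gave an adjusted p of 0.171, and adjusted p = 0.207 with an estimated correlation. In the class switch recombination list 14 of 18 measured members rose, 2 fell and 2 did not pass. Camera gave the class switch list adjusted p = 0.000103, and adjusted p = 0.0643 with an estimated correlation. In the unfolded protein response list 18 of 22 measured members rose, 2 fell and 2 did not pass (Hspa5 1.54 ± 0.097). As a list, unfolded protein response genes gave camera adjusted p = 0.000277, and adjusted p = 0.0524 with an estimated correlation. In the B cell identity list 24 of 30 measured members fell, 1 rose and 5 did not pass (Klf2 -3.03 ± 0.12), and Bcl6, a germinal centre regulator, fell by 2.06 ± 0.11 on the log2 scale. For the B cell identity list the camera adjusted p was 1.62e-08, and adjusted p = 0.0643 with an estimated correlation. Activation and costimulation genes lay below 0 h: 12 of 20 measured members fell, 3 rose and 5 did not pass (median -0.71). Over the activation list camera gave an adjusted p of 0.00338, and adjusted p = 0.0282 with an estimated correlation. Between 0 and 48 h 5207 genes rose and 5299 fell. Library makeup moved as well: Malat1 made up 1.05% of counts at 0 h and 0.195% at 48 h, beside the fall in the Gm42418 share given above. Untreated 48 h replicate 1 stood apart with a Gm42418 share of 2.89%, against 18.0% and 21.4%, and without it 5138 genes rose and 5295 fell.

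With JQ1 at 2 h activation, pro-survival and ribosome biogenesis genes were lower, while unfolded protein response, immediate early and cell cycle brake genes were higher. With an estimated correlation the calls of ribosome biogenesis (adjusted p = 0.146), immediate early (adjusted p = 0.0986) and cell cycle brake genes (adjusted p = 0.297) were lost. Il2ra fell from 92.1 ± 4.98 CPM without JQ1 to 4.65 ± 1.55 CPM with it (-4.27 ± 0.26, adjusted p = 5.03e-12), Bcl2l1 from 73.4 ± 4.95 to 10.9 ± 1.82 CPM (-2.73 ± 0.18, adjusted p = 1.35e-13) and Myc from 103 ± 23.6 to 39.4 ± 2.14 CPM (-1.38 ± 0.20, adjusted p = 6.12e-06). Hexim1, which encodes an inhibitor of the elongation factor P-TEFb and is a known response gene of BET inhibitors, rose 4.35-fold, from 68.2 ± 4.70 to 297 ± 34.5 CPM (2.12 ± 0.13, adjusted p = 1.76e-14), and Brd2 rose by 1.43 ± 0.098, whereas Brd4 was at 0.19 ± 0.097 (adjusted p = 0.11). The largest increases by the naming rule included Hist1h2bc (4.21 ± 0.34), a member of a multigene histone family whose reads are uncertain for that reason, Enc1 (3.32 ± 0.23), the potassium channel gene Kcnc3 (3.10 ± 0.19) and the microtubule regulator gene Stmn1 (3.10 ± 0.16), and the largest decreases included Tmem173, the gene of the DNA-sensing adaptor STING (-3.23 ± 0.26), Itgb3 (-3.16 ± 0.21) and the chemokine receptor gene Ccr6 (-3.06 ± 0.24).

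At 2 h, in the ribosome biogenesis list 25 of 30 measured members fell, 1 rose and 4 did not pass, or 26 and 1 adjusted over the list alone, with the RNA polymerase I subunit gene Polr1b at -2.25 ± 0.17 and Utp20 at -1.45 ± 0.12. Camera gave the ribosome biogenesis list adjusted p = 3.07e-14, and adjusted p = 0.146 with an estimated correlation. In the pro-survival list 8 of 11 measured members fell, 1 rose and 2 did not pass, or 9 and 1 adjusted over the list alone: Bcl2l1 and Bcl2 (-0.46 ± 0.12) fell, and Mcl1 rose (0.54 ± 0.086). As a list, pro-survival genes gave camera adjusted p = 3.3e-05, and adjusted p = 0.0139 with an estimated correlation. In the pro-apoptotic list 5 of 14 measured members rose, 3 fell and 6 did not pass, with Bcl2l11, the gene of Bim, at 1.25 ± 0.12 and Casp3 at 2.09 ± 0.17, and its median (-0.069) and mean (0.022) differed in sign. For the pro-apoptotic list the camera adjusted p was 0.448, and adjusted p = 0.565 with an estimated correlation. Among activation and costimulation genes 10 of 20 measured members fell, 4 rose and 6 did not pass, or 11 and 4 adjusted over the list alone, with Cd44 at -1.79 ± 0.12, Cd86 at -1.26 ± 0.12 and Cd180 at -1.89 ± 0.15. Over the activation list camera gave an adjusted p of 0.000623, and adjusted p = 0.0139 with an estimated correlation. Among immediate early genes 13 of 22 measured members rose, 1 fell and 8 did not pass, or 13 and 2 adjusted over the list alone (Jun 1.73 ± 0.12, Jund 1.65 ± 0.12). Camera gave the immediate early list adjusted p = 2.04e-05, and adjusted p = 0.0986 with an estimated correlation. In the unfolded protein response list 16 of 22 measured members rose, 2 fell and 4 did not pass, with the chaperone genes Calr at 1.35 ± 0.088 and Hspa5 at 0.99 ± 0.096. As a list, unfolded protein response genes gave camera adjusted p = 2.69e-05, and adjusted p = 0.0269 with an estimated correlation. Of the cell cycle brakes 8 of 15 measured members rose, 1 fell and 6 did not pass (Tob1 3.04 ± 0.25, Gadd45a 2.55 ± 0.23, Cdkn1a 0.87 ± 0.20). For the cell cycle brake list the camera adjusted p was 0.0036, and adjusted p = 0.297 with an estimated correlation. In the glycolysis and amino acid uptake list 10 of 22 measured members rose, 1 fell and 11 did not pass, or 12 and 1 adjusted over the list alone (Pkm 1.15 ± 0.14, Aldoa 1.02 ± 0.12). Over the glycolysis and amino acid uptake list camera gave an adjusted p of 0.0036, and adjusted p = 0.475 with an estimated correlation. Of the BET inhibitor response markers 5 of 8 measured members rose, 1 fell and 2 did not pass, or 6 and 1 adjusted over the list alone, and the member that fell was Zmynd8 (-1.68 ± 0.15). Camera gave the BET response marker list adjusted p = 0.00465, and adjusted p = 0.0599 with an estimated correlation. The NF-kB list was not called at 2 h: 9 of 26 measured members fell, 5 rose and 12 did not pass, and Traf1 fell (-1.45 ± 0.13), whereas Nfkbia, the gene of an NF-kB inhibitor, rose (1.06 ± 0.098). As a list, NF-kB genes gave camera adjusted p = 0.227, and adjusted p = 0.635 with an estimated correlation. The B cell identity list was not called either: 15 of 30 measured members fell, 6 rose and 9 did not pass, or 16 and 6 adjusted over the list alone, and the complement receptor gene Cr2 (-1.43 ± 0.11) and Pax5 (-0.63 ± 0.095) fell and Klf2 rose (2.10 ± 0.12). For the B cell identity list the camera adjusted p was 0.0646, and adjusted p = 0.635 with an estimated correlation. Irf4 stood at 0.0024 ± 0.10 (adjusted p = 0.989), and with library totals in place of composition factors at -0.27 (adjusted p = 0.038, range over all alternatives 0.038 to 1). In all, 2947 genes were higher and 3134 lower with JQ1 at 2 h, of which 1001 and 1322 differed at least 2-fold. With library totals the counts were 1619 and 4768, so that 74.7% of calls were lower against 51.5%.

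At 8 h the p53 targets, interferon-stimulated genes and NF-kB genes were lower with JQ1, and cholesterol synthesis genes were higher. Cdkn1a fell from 52.1 ± 4.28 to 16.4 ± 2.99 CPM (-1.67 ± 0.17, adjusted p = 1.11e-08), the death receptor gene Fas by 2.51 ± 0.29 and Zmat3 by 1.46 ± 0.17 on the log2 scale. In the p53 target list 16 of 19 measured members fell, 0 rose and 3 did not pass, or 17 and 1 adjusted over the list alone. Over the p53 target list camera gave an adjusted p of 1.51e-13, and adjusted p = 0.000165 with an estimated correlation. Ebi3, which encodes a subunit shared by several cytokines, fell from 118 ± 11.0 to 11.0 ± 4.52 CPM (-3.42 ± 0.20, adjusted p = 4.54e-12), Il2ra from 79.4 ± 7.34 to 8.59 ± 4.37 CPM (-3.20 ± 0.22) and Myc from 24.7 ± 2.33 to 10.7 ± 2.83 CPM (-1.21 ± 0.23, adjusted p = 0.000558). Kcnc3 (2.83 ± 0.19), Hexim1 (2.30 ± 0.13), Stmn1 (2.13 ± 0.16) and Brd2 (0.83 ± 0.097) were higher.

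In the interferon-stimulated list at 8 h 14 of 27 measured members fell, 1 rose and 12 did not pass, or 16 and 1 adjusted over the list alone: Oasl1 stood at -3.34 ± 0.21, the RNA sensor gene Ifih1 at -3.48 ± 0.33 and Isg15 at -2.35 ± 0.22, while Stat2, a signalling protein gene, rose (0.93 ± 0.13). Camera gave the interferon-stimulated list adjusted p = 1.05e-10, and adjusted p = 5.71e-05 with an estimated correlation. In the NF-kB list 12 of 26 measured members fell, 0 rose and 14 did not pass, or 13 and 1 adjusted over the list alone (Ltb -1.31 ± 0.18, Traf1 -0.81 ± 0.13). As a list, NF-kB genes gave camera adjusted p = 3.85e-07, and adjusted p = 0.0243 with an estimated correlation. In the activation list 10 of 20 measured members fell, 2 rose and 8 did not pass, or 11 and 2 adjusted over the list alone (Cd44 -0.78 ± 0.11, Cd86 -0.78 ± 0.14). For the activation list the camera adjusted p was 4.26e-06, and adjusted p = 0.00084 with an estimated correlation. In the pro-survival list 8 of 11 measured members fell, 1 rose and 2 did not pass (Bcl2l1 -0.79 ± 0.15, Cflar -0.70 ± 0.099, Bcl2 -0.50 ± 0.11). Over the pro-survival list camera gave an adjusted p of 4.63e-05, and adjusted p = 0.00876 with an estimated correlation. The pro-apoptotic list was lower too: 5 of 14 measured members fell, 1 rose and 8 did not pass, or 6 and 1 adjusted over the list alone (Bbc3 -0.73 ± 0.12, Bax -0.82 ± 0.17). It shares Bbc3, Bax, Pmaip1 and Fas with the p53 target list, so the results of these lists are not independent. The pro-apoptotic call was lost without JQ1 8 h replicate 1 (adjusted p = 0.0555, range over all alternatives 0.0155 to 0.0555). Camera gave the pro-apoptotic list adjusted p = 0.0279, and adjusted p = 0.058 with an estimated correlation. Cholesterol synthesis genes were higher: 13 of 21 measured members rose, 0 fell and 8 did not pass, or 18 and 0 adjusted over the list alone, with Sqle at 0.67 ± 0.11, Hmgcs1 at 0.57 ± 0.10 and the LDL receptor gene Ldlr at 0.50 ± 0.11. As a list, cholesterol synthesis genes gave camera adjusted p = 1.78e-07, and adjusted p = 0.0423 with an estimated correlation. In the ribosome biogenesis list 10 of 30 measured members fell, 0 rose and 20 did not pass, or 11 and 1 adjusted over the list alone (Dkc1 -0.55 ± 0.11). For the ribosome biogenesis list the camera adjusted p was 0.000864, and adjusted p = 0.497 with an estimated correlation. In the unfolded protein response list 8 of 22 measured members rose, 4 fell and 10 did not pass, with Hspa5 at 0.79 ± 0.096 and the stress-induced pseudokinase gene Trib3 at -0.89 ± 0.16. Over the unfolded protein response list camera gave an adjusted p of 0.0135, and adjusted p = 0.116 with an estimated correlation. The B cell identity list was not called: 5 of 30 measured members rose, 4 fell and 21 did not pass, or 5 and 6 adjusted over the list alone, with Ms4a1, the gene of CD20, at 0.74 ± 0.088 and Cr2 at -1.46 ± 0.10. Camera gave the B cell identity list adjusted p = 0.738, and adjusted p = 0.893 with an estimated correlation. The BET inhibitor response markers were higher at 8 h: 3 of 8 measured members rose, 1 fell and 4 did not pass (median 0.89). As a list, BET response marker genes gave camera adjusted p = 0.000252, and adjusted p = 0.0144 with an estimated correlation. Brd4 was at -0.030 ± 0.098 (adjusted p = 0.878) and Irf4 at -0.27 ± 0.10 (adjusted p = 0.0672). In all, 1249 genes were higher and 1314 lower, 225 and 494 of them at least 2-fold. Without JQ1 8 h replicate 1 the counts were 819 and 827, and a fit of the 8 h groups alone gave 1893 higher genes. With library totals 61.6% of calls were lower, against 51.3%. In a simulated 8 h comparison of 13682 genes 9.42% of the calls were false. Far fewer genes were changed in that simulation than were called here, so the share does not carry over to these counts.

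**Figure D2:**
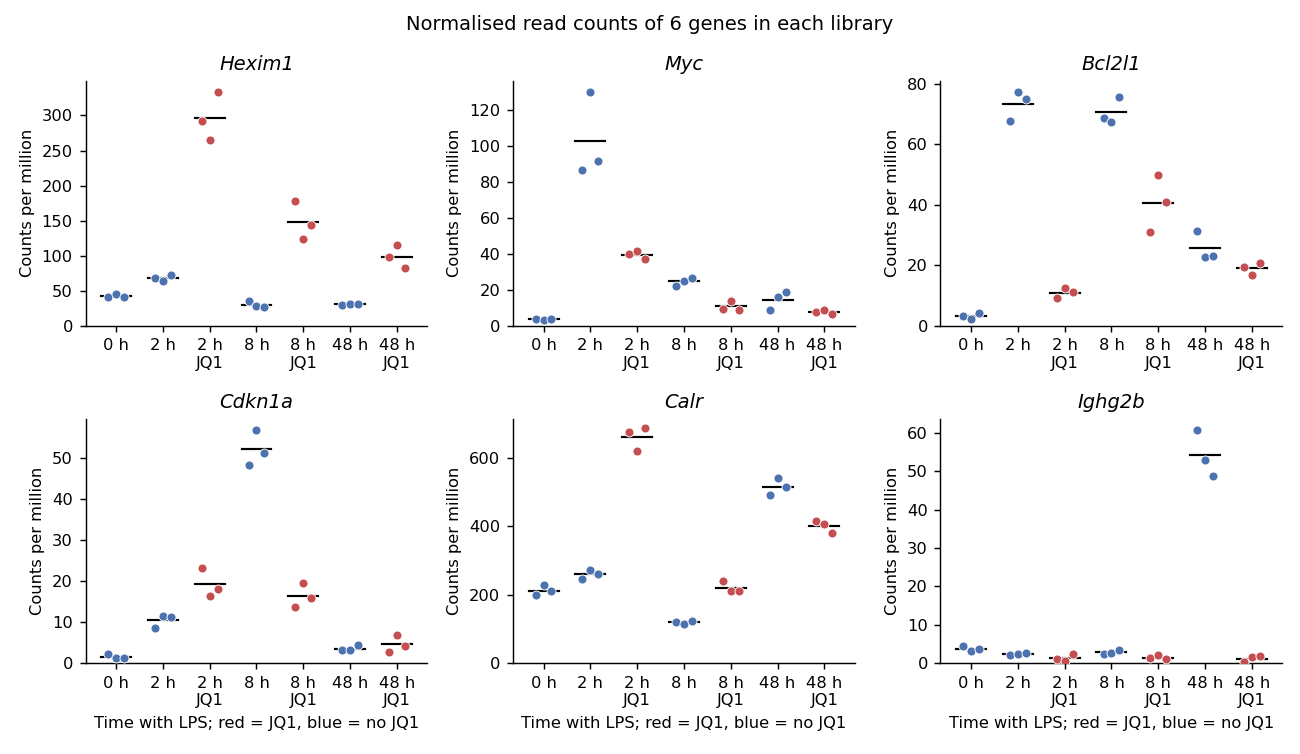
Counts scaled to a common library size (CPM, y axis, linear from 0) of Hexim1, Myc, Bcl2l1, Cdkn1a, Calr and Ighg2b in each of the 21 libraries by group, where points are libraries, lines are group means, blue is without JQ1 and red is with JQ1. With JQ1 at 2 h Hexim1 and Calr were higher and Myc and Bcl2l1 lower, and at 48 h Ighg2b stood at 54.2 ± 6.00 CPM without JQ1 and 1.23 ± 0.828 CPM with it (mean ± SD, n = 3).

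By 48 h the lists of ribosome biogenesis, cell division and class switch genes, which had risen from 0 h, were lower in cells with JQ1. Cell cycle brakes were higher. With an estimated correlation the calls of G2/M (adjusted p = 0.31) and class switch genes (adjusted p = 0.0924) with JQ1 were lost. So were those of ribosome biogenesis (adjusted p = 0.0584) and class switch genes (adjusted p = 0.0643) against 0 h. Ighg2b, an antibody heavy chain constant gene reached by class switching, was at 54.2 ± 6.00 CPM without JQ1 and 1.23 ± 0.828 CPM with it (-5.40 ± 0.29, adjusted p = 2.62e-15). The JQ1 libraries held 0.28 to 1.78 CPM, near the level of 3 counts (0.669 to 0.839 CPM). Reads at the 3' end do not separate transcripts of switched cells from others that share that end, so switching itself was not measured. Zbtb32 fell from 83.8 ± 15.2 to 3.21 ± 2.48 CPM (-4.63 ± 0.29), the amino acid transporter gene Slc7a3 by 4.90 ± 0.42 and Cd93, a surface receptor gene, by 4.38 ± 0.22 on the log2 scale. S1pr1, whose receptor guides the exit of lymphocytes from tissue, rose from 13.9 ± 1.99 to 116 ± 33.5 CPM (3.07 ± 0.16, adjusted p = 9.45e-15), and Clec2i (3.48 ± 0.22), Kcnc3 (3.41 ± 0.21), Klhl24 (2.84 ± 0.19) and Hexim1 (1.69 ± 0.13) were also higher. Among genes of class switching and plasma cells, Aicda (-3.12 ± 0.43), Prdm1 (-0.91 ± 0.18), Xbp1 (-0.66 ± 0.14) and Jchain (-3.56 ± 0.40), which encodes the joining chain of secreted antibodies, were lower. The Aicda level with JQ1, 1.12 ± 1.11 CPM, rests on few counts. Irf4 stood at 102 ± 4.28 CPM without JQ1 and 83.5 ± 9.12 CPM with it, with an adjusted p of 2.03e-05 to 0.45 over the alternatives. The plasma cell list as a whole was not called at 48 h: 11 of 21 measured members fell, 4 rose and 6 did not pass (camera adjusted p = 0.126, 0.164 with an estimated correlation).

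In the ribosome biogenesis list at 48 h 30 of 30 measured members fell, 0 rose and 0 did not pass (Ppan -1.94 ± 0.13, Wdr12 -1.93 ± 0.12). For the ribosome biogenesis list the camera adjusted p was 1.12e-25, and adjusted p = 0.0384 with an estimated correlation. In the G1/S and DNA replication list 30 of 30 measured members fell, 0 rose and 0 did not pass (Mcm5 -1.70 ± 0.13, Ccnd3 -1.52 ± 0.11). Over the G1/S list camera gave an adjusted p of 3.76e-11, and adjusted p = 0.0441 with an estimated correlation. In the G2/M and mitosis list 24 of 25 measured members fell, 0 rose and 1 did not pass (Cdc20 -1.91 ± 0.23, Aurka -1.63 ± 0.19). Camera gave the G2/M list adjusted p = 3.03e-05, and adjusted p = 0.31 with an estimated correlation. Ccnd2 fell from 2411 ± 663 to 588 ± 241 CPM (-2.03 ± 0.26). Of the cell cycle brakes 11 of 15 measured members rose, 0 fell and 4 did not pass, with the antiproliferative genes Btg1 at 2.12 ± 0.13 and Btg2 at 1.63 ± 0.14 and the CDK inhibitor locus Cdkn2a at 2.31 ± 0.20, while Cdkn1a was at 0.37 ± 0.28 (adjusted p = 0.25). As a list, cell cycle brake genes gave camera adjusted p = 3.83e-09, and adjusted p = 0.0384 with an estimated correlation. In the glycolysis and amino acid uptake list 19 of 22 measured members fell, 1 rose and 2 did not pass (Tpi1 -1.64 ± 0.15, Pgk1 -1.15 ± 0.11). For the glycolysis and amino acid uptake list the camera adjusted p was 7.07e-07, and adjusted p = 0.141 with an estimated correlation. Unfolded protein response genes were lower: 16 of 22 measured members fell, 1 rose and 5 did not pass (Pdia6 -1.11 ± 0.11, Hspa5 -0.95 ± 0.096). Over the unfolded protein response list camera gave an adjusted p of 0.000659, and adjusted p = 0.0441 with an estimated correlation. Of class switch recombination genes 15 of 18 measured members fell, 1 rose and 2 did not pass (Ung -1.75 ± 0.19). Camera gave the class switch list adjusted p = 0.000834, and adjusted p = 0.0924 with an estimated correlation. Interferon-stimulated genes were lower: 20 of 27 measured members fell, 1 rose and 6 did not pass (Oasl1 -4.62 ± 0.26). As a list, interferon-stimulated genes gave camera adjusted p = 0.00107, and adjusted p = 0.0345 with an estimated correlation. Immediate early genes were higher: 13 of 22 measured members rose, 1 fell and 8 did not pass (Egr1 2.75 ± 0.15, Dusp2 1.82 ± 0.13). For the immediate early list the camera adjusted p was 7.06e-05, and adjusted p = 0.118 with an estimated correlation. In the B cell identity list 16 of 30 measured members rose, 6 fell and 8 did not pass (Ciita 1.25 ± 0.13, Bcl6 0.93 ± 0.13, Ms4a1 0.79 ± 0.088), a call lost with library totals (adjusted p = 0.138, range over all alternatives 0.000229 to 0.138). Over the B cell identity list camera gave an adjusted p of 0.00652, and adjusted p = 0.373 with an estimated correlation. Pax5 was at 0.034 ± 0.092 (adjusted p = 0.774), and with library totals at -0.29 (adjusted p = 0.0193, range 0.0193 to 0.995). The pro-survival list was not called: 5 of 11 measured members fell, 4 rose and 2 did not pass, and Bcl2 fell (-0.86 ± 0.11) and Mcl1 rose (0.72 ± 0.087), and the pro-apoptotic gene Bcl2l11 rose (1.19 ± 0.13). Camera gave the pro-survival list adjusted p = 0.715, and adjusted p = 0.8 with an estimated correlation. The BET inhibitor response markers were not called at 48 h: 4 of 8 measured members rose, 2 fell and 2 did not pass. As a list, BET response marker genes gave camera adjusted p = 0.217, and adjusted p = 0.323 with an estimated correlation. Myc was at 7.65 ± 0.888 CPM with JQ1 and 14.4 ± 5.30 CPM without (-0.89 ± 0.28, adjusted p = 0.00886), a call lost in limma (adjusted p = 0.0862), with upper-quartile factors (0.0563) and without JQ1 48 h replicate 3 (0.0797, range over all alternatives 5.68e-07 to 0.0862). Brd4 was at -0.053 ± 0.099 (adjusted p = 0.661) and Brd2 rose (0.82 ± 0.098). These gene groups moved beside a difference in library makeup: the Gm42418 share given above was higher with JQ1 at 48 h, and the nuclear non-coding RNA Malat1 made up 1.39 ± 0.523% of counts with JQ1 and 0.195 ± 0.044% without (3.17 ± 0.26). In all, 3645 genes were higher and 4459 lower at 48 h, 1702 and 1887 of them at least 2-fold. With library totals 2139 genes were higher and 74.6% of calls were lower, with upper-quartile factors 43.1%, against 55.0%. In a simulated 48 h comparison of 13682 genes 11.5% of the calls were false. That simulation also changed far fewer genes than were called at 48 h, so its share does not carry over to the counts above.

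**Figure D3:**
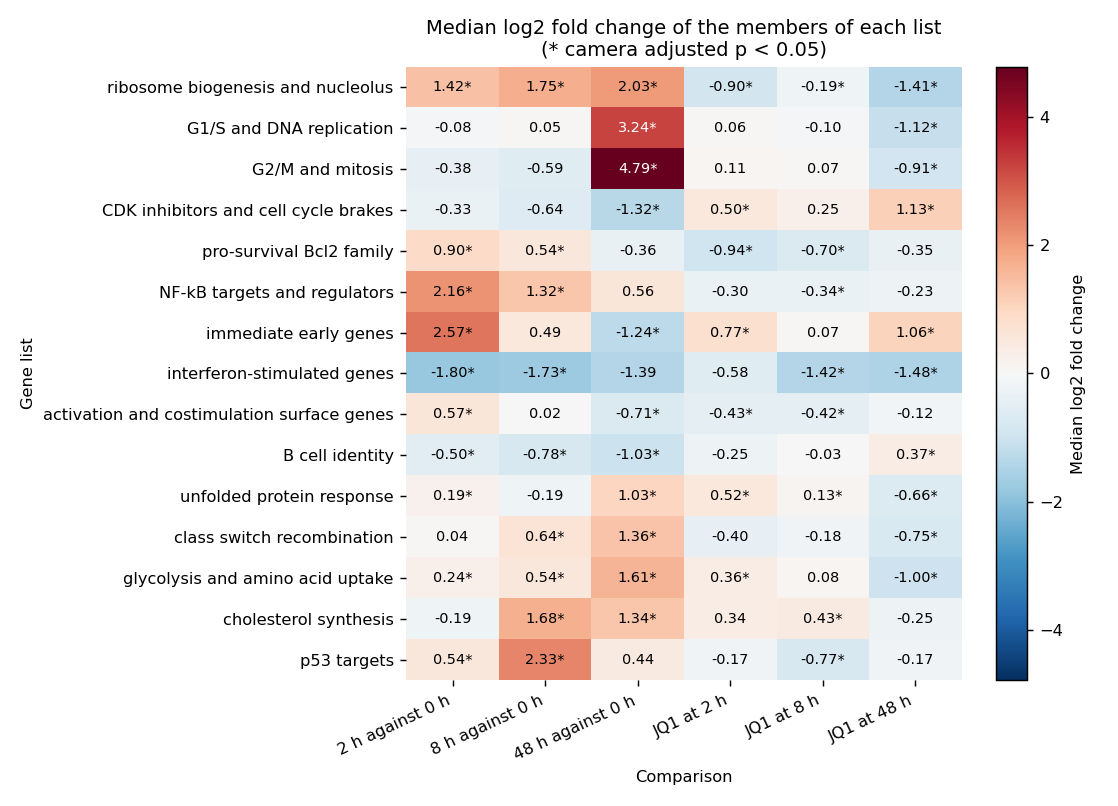
Heat map of the median log2 fold change (colour and printed value) of the members of 15 gene lists (rows) in the 3 comparisons with 0 h and the 3 comparisons with JQ1 (columns), where an asterisk marks a camera adjusted p under 0.05. The ribosome biogenesis list was 2.03 above 0 h at 48 h and -1.41 with JQ1 at 48 h, and the unfolded protein response list was 0.52 with JQ1 at 2 h and -0.66 at 48 h.

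Whether the effect of JQ1 itself differed between times was tested as a difference of log2 fold changes in the same model. Between 2 and 48 h the effect on the unfolded protein response list became lower: 17 of 22 measured members fell, 0 rose and 5 did not pass (median -1.18). For the unfolded protein response list the camera adjusted p was 1.3e-11, and adjusted p = 0.00162 with an estimated correlation. So did that on glycolysis and amino acid uptake, where 19 of 22 measured members fell, 0 rose and 3 did not pass, or 21 and 0 adjusted over the list alone (median -1.35). Over the glycolysis and amino acid uptake list camera gave an adjusted p of 5.23e-13, and adjusted p = 0.0419 with an estimated correlation. The effect on the pro-survival list was less negative at 48 h than at 2 h: 8 of 11 measured members rose, 1 fell and 2 did not pass (median 1.08). Camera gave the pro-survival list adjusted p = 0.000362, and adjusted p = 0.0269 with an estimated correlation. Between 8 and 48 h the effect on ribosome biogenesis became more negative: 30 of 30 measured members fell, 0 rose and 0 did not pass (median -1.14). As a list, ribosome biogenesis genes gave camera adjusted p = 1.46e-20, and adjusted p = 0.0759 with an estimated correlation. That on G1/S and DNA replication moved likewise, where 19 of 30 measured members fell, 0 rose and 11 did not pass, or 20 and 0 adjusted over the list alone (median -1.14). For the G1/S list the camera adjusted p was 1.07e-07, and adjusted p = 0.107 with an estimated correlation. Between 2 and 8 h the immediate early genes differed: 11 of 22 measured members fell, 0 rose and 11 did not pass, or 14 and 0 adjusted over the list alone (median -0.83). Over the immediate early list camera gave an adjusted p of 2.95e-08, and adjusted p = 0.0316 with an estimated correlation. For the p53 targets 6 of 19 measured members fell, 2 rose and 11 did not pass, or 8 and 2 adjusted over the list alone (median -0.53). Camera gave the p53 target list adjusted p = 3.15e-05, and adjusted p = 0.0278 with an estimated correlation. Some of these effects turned over the time course: between 2 and 8 h that on ribosome biogenesis became less negative, where 20 of 30 measured members rose, 0 fell and 10 did not pass, or 25 and 1 adjusted over the list alone (median 0.61). As a list, ribosome biogenesis genes gave camera adjusted p = 1.23e-13, and adjusted p = 0.141 with an estimated correlation. Between 8 and 48 h the immediate early genes became higher: 11 of 22 measured members rose, 2 fell and 9 did not pass, or 12 and 2 adjusted over the list alone (median 1.05). For the immediate early list the camera adjusted p was 0.000443, and adjusted p = 0.122 with an estimated correlation. The p53 targets did as well: 9 of 19 measured members rose, 2 fell and 8 did not pass (median 0.85). Over the p53 target list camera gave an adjusted p of 0.00137, and adjusted p = 0.0759 with an estimated correlation. Cdkn1a, higher with JQ1 at 2 h and lower at 8 h, differed by -2.55 ± 0.26 between these times, Stmn1 by -4.35 ± 0.21 and Ighg2b by -4.50 ± 0.60 between 2 and 48 h, and Mgll by 3.37 ± 0.32 and S1pr1 by 2.87 ± 0.23 between 8 and 48 h. The effect differed for 2072 genes between 2 and 8 h, 5661 between 8 and 48 h and 5825 between 2 and 48 h. The share of these that were lower at the later time was 45.9%, 56.3% and 53.3%, and it became 15.8% between 2 and 8 h and 75.9% between 8 and 48 h with library totals, and 39.5% between 8 and 48 h and 37.9% between 2 and 48 h with upper-quartile factors.

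Part of the response to JQ1 was shared between times. At all 3 times 561 genes were higher with JQ1, Kcnc3 and Hexim1 among them, and 506 were lower, with Il2ra, Ebi3, Cd93 and Ccr6 picked from these after their values were seen. Of the genes higher at 2 h 996 were also higher at 8 h, where independent lists of these sizes would share 265, and 840 were lower at both times, where independent lists would share 296 (one-sided Fisher's exact p = 6.38e-256 over genes, which are not independent replicates). Between 8 and 48 h 665 genes were higher at both times (independent lists 327, exact p = 1.82e-101) and 716 lower at both (independent lists 421, exact p = 6.13e-70). With library totals 600 genes were higher at both 2 and 8 h and 348 at both 8 and 48 h. Without JQ1 8 h replicate 1 the lower genes shared by 2 and 8 h numbered 551, and those shared by 8 and 48 h 460, with 424 higher at both 8 and 48 h.

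Changes with JQ1 were set against the changes from 0 h, in which effects of LPS and of culture cannot be separated. The genes lower with JQ1 at 8 and 48 h were more often than for independent lists those raised from 0 h. At 2 h excesses lay in both directions. Genes raised from 0 h and lower with JQ1 numbered 1012 at 2 h, 627 at 8 h and 3589 at 48 h. Independent lists would share 786, 341 and 1669.9. Il2ra, Myc, Bcl2l1 and Cd86 belonged to these genes at 2 h, Cdkn1a, Myc, Bcl2l1 and Traf1 at 8 h, and Zbtb32, Prdm1, Aicda and Xbp1 at 48 h. Genes lowered from 0 h and higher with JQ1 numbered 743, 682 and 3051, with 765, 319 and 1389 for independent lists, so that at 2 h the count lay below that of independent lists. S1pr1 and Bcl6 were among them at 48 h. At 2 h genes that moved the same way from 0 h and with JQ1 also exceeded independent lists. They numbered 883 raised and higher with JQ1 (independent lists 739) and 868 lowered and lower (independent lists 814). At 8 and 48 h such genes numbered 168 and 110 raised and higher (independent lists 324 and 1365) and 315 and 269 lowered and lower (independent lists 336 and 1699), below independent lists. The comparisons share the untreated libraries of each time, and in 20 simulations without any effect the shared count did not exceed 1, a value for chance alone that does not show how far shared controls add to the overlap of real changes. The covariance of the log2 fold changes across genes was -0.048, -0.18 and -0.98 at 2, 8 and 48 h, beside simulated values of -0.031, -0.032 and -0.023. With 3 libraries the controls could not be split into parts of 2, so part of each excess may come from the shared controls, and without JQ1 8 h replicate 1 the count at 8 h was 413, while a fit of the groups compared alone gave 1009.

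Some of the fixed lists held few measured members or were not called. For BET proteins and P-TEFb at 8 h 3 of 11 measured members rose, 0 fell and 8 did not pass, and the call was lost with a stricter low-count filter (adjusted p = 0.102, without untreated 8 h replicate 1 adjusted p = 0.101, range over all alternatives 0.0132 to 0.102). Camera gave the BET protein list adjusted p = 0.0279, and adjusted p = 0.121 with an estimated correlation. For the Myc network at 48 h 5 of 10 measured members rose, 2 fell and 3 did not pass. As a list, Myc network genes gave camera adjusted p = 0.0528, and adjusted p = 0.322 with an estimated correlation. For plasma cell differentiation 11 of 21 measured members fell, 4 rose and 6 did not pass. For the plasma cell list the camera adjusted p was 0.126, and adjusted p = 0.164 with an estimated correlation. For lysosome and autophagy 12 of 27 measured members rose, 6 fell and 9 did not pass. Over the lysosome list camera gave an adjusted p of 0.165, and adjusted p = 0.37 with an estimated correlation. Markers of other cells, most of which the purification of B cells would remove, were sparse. Of the T cell markers only Lck and Cd2 were measured, and mouse B cells express Cd2 as well: at 2 h Lck was at 10.3 ± 0.891 CPM without JQ1 and 1.99 ± 0.322 CPM with it, and Cd2 at 39.4 ± 5.16 and 21.8 ± 1.09 CPM. With JQ1 2 of 2 measured members fell, 0 rose and 0 did not pass at 2 h, a call lost under 8 alternatives, such as a stricter low-count filter (adjusted p = 0.0782) and leaving out JQ1 2 h replicate 2 (0.076, range over all alternatives 0.0266 to 0.13). Camera gave the T cell list adjusted p = 0.0456, and adjusted p = 0.157 with an estimated correlation. At 8 h 2 of 2 measured members fell, 0 rose and 0 did not pass with JQ1 (median -1.58), a call lost when thinned with Gm42418 left out (adjusted p = 0.0779), in DESeq2 (0.0513) and without the low-count filter (0.28, range over all alternatives 0.00149 to 0.28). As a list, T cell genes gave camera adjusted p = 0.00671, and adjusted p = 0.0423 with an estimated correlation. With JQ1 at 48 h 2 of 2 measured members fell, 0 rose and 0 did not pass. For the T cell list the camera adjusted p was 0.275, and adjusted p = 0.373 with an estimated correlation. From 0 to 8 h without JQ1 2 of 2 measured members fell, 0 rose and 0 did not pass (median -2.48), a call lost without the low-count filter (adjusted p = 0.478, range over all alternatives 8.42e-05 to 0.478). Over the T cell list camera gave an adjusted p of 0.000233, and adjusted p = 0.00978 with an estimated correlation. From 0 to 48 h 2 of 2 measured members fell, 0 rose and 0 did not pass (median -2.18), a call lost in limma (adjusted p = 0.0799), in DESeq2 (0.171) and without the low-count filter (0.492, range over all alternatives 0.00654 to 0.492). Camera gave the T cell list adjusted p = 0.0163, and adjusted p = 0.0643 with an estimated correlation. Of the myeloid list with JQ1 at 48 h, 1 of 4 measured members fell, 0 rose and 3 did not pass. As a list, myeloid genes gave camera adjusted p = 0.615, and adjusted p = 0.636 with an estimated correlation. Of the dendritic and NK cell list with JQ1 at 48 h, 2 of 3 measured members fell, 0 rose and 1 did not pass. For the dendritic and NK cell list the camera adjusted p was 0.469, and adjusted p = 0.585 with an estimated correlation. That list was called at 8 h, where 1 of 3 measured members fell, 0 rose and 2 did not pass, or 2 and 0 adjusted over the list alone (median -1.27), a call lost under 6 alternatives, such as leaving out untreated 8 h replicate 2 (adjusted p = 0.0609) or JQ1 8 h replicate 1 (0.08, range over all alternatives 0.011 to 0.287). Over the dendritic and NK cell list camera gave an adjusted p of 0.0145, and adjusted p = 0.067 with an estimated correlation. Of the erythroid and platelet list with JQ1 at 48 h, 2 of 3 measured members fell, 1 rose and 0 did not pass. Camera gave the erythroid and platelet list adjusted p = 0.49, and adjusted p = 0.636 with an estimated correlation. Of the marginal zone and B1 list with JQ1 at 48 h, 3 of 10 measured members fell, 1 rose and 6 did not pass, or 3 and 0 adjusted over the list alone. As a list, marginal zone and B1 genes gave camera adjusted p = 0.641, and adjusted p = 0.636 with an estimated correlation. None of the mitochondrially encoded transcripts could be tested, since their rows held 0 counts in every library.

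In the mouse assembly GRCm38 (mm10), the genes plotted lie as follows in the RefSeq annotation, all as protein-coding genes: Hexim1 (ENSMUSG00000048878, chromosome 11, 103116325 to 103119725), Myc (ENSMUSG00000022346, chromosome 15, 61985341 to 61990361), Bcl2l1 (ENSMUSG00000007659, chromosome 2, 152758732 to 152833803), Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722) and Calr (ENSMUSG00000003814, chromosome 8, 84842088 to 84846931). Ighg2b (ENSMUSG00000076613, chromosome 12, 113304314 to 113307933) is annotated as an immunoglobulin constant segment, and Il2ra is at ENSMUSG00000026770, chromosome 2, 11642792 to 11693194.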

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

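Differences of the JQ1 effect between times were tested as planned, while the tests below against technical causes and the counts over other splits of the samples were chosen after the results were seen. The JQ1 effect differed for 2072 genes between 2 and 8 h, 5661 between 8 and 48 h and 5825 between 2 and 48 h by edgeR's quasi-likelihood test. Limma on permuted residuals, with 100 permutations counting the real order, gave 2844, 5081 and 5106 genes for the real data. The other orders gave at most 786, 808 and 0, so that 1 of 100, the real order, gave as many. A random order of these libraries thus seldom gives such counts. The permutations treat libraries of unlike depth as exchangeable. They also cannot address chance between mice or cultures, since the libraries of a group may be technical repeats. For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes. The real splits gave 6081, 2563 and 8104 genes for JQ1 at 2, 8 and 48 h, with at most 0, 0 and 6 in another split, and 7099, 7161 and 10506 for 2, 8 and 48 h against 0 h, with at most 0 in each.

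Lists whose JQ1 effect differed are given by the pair of times with the smallest adjusted p, as the median over members of the later minus the earlier log2 fold change. From 2 to 48 h the effect became lower for glycolysis and amino acid uptake (-1.35, camera adjusted p = 5.23e-13, adjusted p = 0.0419 with an estimated correlation). It also became lower for the unfolded protein response (-1.18, camera adjusted p = 1.3e-11, adjusted p = 0.00162 with an estimated correlation). Over the same span it became higher for B cell identity (0.50, camera adjusted p = 6.7e-05, adjusted p = 0.286 with an estimated correlation) and pro-survival genes (1.08, camera adjusted p = 0.000362, adjusted p = 0.0269 with an estimated correlation). For activation genes it became higher too (0.59, camera adjusted p = 0.000476, adjusted p = 0.0121 with an estimated correlation). From 8 to 48 h the effect became lower for ribosome biogenesis (-1.14, camera adjusted p = 1.46e-20, adjusted p = 0.0759 with an estimated correlation). G1/S (-1.14, camera adjusted p = 1.07e-07, adjusted p = 0.107 with an estimated correlation) and G2/M genes (-1.10, camera adjusted p = 0.00208, adjusted p = 0.464 with an estimated correlation) moved the same way. Cholesterol synthesis (-0.63, camera adjusted p = 0.000143, adjusted p = 0.122 with an estimated correlation) and class switch genes (-0.64, camera adjusted p = 0.0135, adjusted p = 0.196 with an estimated correlation) did as well. Cell cycle brakes became higher between 8 and 48 h (0.96, camera adjusted p = 6.62e-06, adjusted p = 0.101 with an estimated correlation). From 2 to 8 h the effect became lower for immediate early genes (-0.83, camera adjusted p = 2.95e-08, adjusted p = 0.0316 with an estimated correlation) and p53 targets (-0.53, camera adjusted p = 3.15e-05, adjusted p = 0.0278 with an estimated correlation). Interferon-stimulated genes (-0.76, camera adjusted p = 0.00582, adjusted p = 0.0278 with an estimated correlation) and pro-apoptotic genes (-0.20, camera adjusted p = 0.00227, adjusted p = 0.0278 with an estimated correlation, a median that turned positive with library totals) shared that direction.

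Of the 87 genes named in the comparisons with JQ1, the effect differed between some pair of times for 75 and did not pass for 12, and each that differed is given with its log2 difference at the pair with the smallest adjusted p. From 2 to 48 h the effect became lower for Stmn1 (-4.35), Jchain (-3.81), Hist1h2bc (-2.93), Oasl1 (-2.82), Pkm (-2.36), Ccnd3 (-2.26), Tpi1 (-2.10), Hspa5 (-1.94), Pdia6 (-1.83), Isg15 (-1.79), Casp3 (-1.77), Jund (-1.75), Calr (-1.71), Aldoa (-1.64), Bbc3 (-1.53), Ccnd2 (-1.47), Nfkbia (-1.41), Xbp1 (-1.38), Ebi3 (-1.25), Tob1 (-1.09), Brd2 (-0.61) and Bcl2 (-0.40). It became higher over that span for S1pr1 (3.53), Clec2i (2.85), Malat1 (2.67), Egr1 (2.51), Cd180 (2.30), Bcl2l1 (2.29), Ciita (1.97), Btg1 (1.88), Cd44 (1.22), Cd86 (0.83), Pax5 (0.66), Zmynd8 (0.64) and Ms4a1 (0.39). From 8 to 48 h the effect became lower for Ighg2b (-4.47), Zbtb32 (-3.26), Slc7a3 (-3.17), Cdc20 (-1.96), Cd93 (-1.78), Aurka (-1.58), Ung (-1.54), Ppan (-1.54), Wdr12 (-1.42), Pgk1 (-1.37), Mcm5 (-1.36), Ldlr (-1.29), Dkc1 (-1.16), Sqle (-0.99), Hmgcs1 (-0.82), Cd2 (-0.79), Traf1 (-0.69) and Hexim1 (-0.61). It became higher over that span for Klhl24 (2.28), Zmat3 (2.05), Ltb (1.74), Gadd45a (1.28), Btg2 (1.26), Dusp2 (1.16), Bcl2l11 (1.10), Cflar (0.86), Bcl6 (0.73), Cr2 (0.64) and Mcl1 (0.48). From 2 to 8 h the effect became lower for Enc1 (-3.77), Cdkn1a (-2.55), Jun (-1.69), Klf2 (-1.43) and Trib3 (-0.76). It became higher over that span for Tmem173 (1.98), Itgb3 (1.68), Polr1b (1.67), Ccr6 (1.33), Utp20 (1.22) and Il2ra (1.07). Those that did not pass, with the difference and adjusted p at the pair with the smallest p, were Aicda (8 to 48 h, -1.97, 0.121), Bax (2 to 8 h, -0.61, 0.138), Brd4 (2 to 48 h, -0.25, 0.157), Cdkn2a (2 to 48 h, 4.43, 0.135), Fas (8 to 48 h, 0.85, 0.401), Ifih1 (8 to 48 h, 0.84, 0.16), Irf4 (2 to 48 h, -0.29, 0.113), Kcnc3 (8 to 48 h, 0.58, 0.0938), Lck (8 to 48 h, 1.00, 0.196), Myc (2 to 48 h, 0.49, 0.283), Prdm1 (2 to 8 h, 1.24, 0.102) and Stat2 (2 to 8 h, -0.34, 0.264).

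At 48 h the effect of JQ1 ran against the change from 0 h: 3589 genes raised from 0 h were lower with JQ1, where independent lists would share 1669.9, and 110 raised genes were higher with JQ1. Depth and the Gm42418 share differed between the 48 h groups. With Gm42418 left out and every library thinned to equal depth, 2790 raised and lower genes were found among 12144, where independent lists would share 1165. The excess thus remained at equal depth and without that row. The thinned comparisons still shared the untreated libraries, and a shift in other rows would remain. A cause in library makeup is therefore not excluded. Random spread of the shared untreated libraries alone gave a simulated covariance of the log2 fold changes of -0.023, and the observed value was -0.98. A shift common to the untreated 48 h libraries was not simulated, so shared controls stay open as part of the cause. RNA quality or input that differed between the groups stays open, since Gm42418 itself was 2.00 higher on the log2 scale with JQ1 at 48 h and the design confounds it with treatment. That JQ1 holds back the later response to LPS is the biological hypothesis the design gives, and it was not tested apart from these libraries.

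Unfolded protein response genes were higher with JQ1 at 2 h and lower at 48 h. A change of scaling between libraries could shift all medians together. The 4 other scalings tried were median-of-ratios factors, upper-quartile factors, library totals and Gm42418 left out. Under these the median difference of the list between 48 and 2 h was at most -0.97, against -1.18. They moved the differences of all genes by a median of at most 0.22, so they could not have reversed that of the list. This argues against these choices of scaling only, and without a spike-in a larger shift was not tested. RNA quality at 48 h, as above, stays open for the later part, and an effect of JQ1 that changes with time is the biological hypothesis, untested beyond the difference itself.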

How the results depend on the processing

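All 22 counts of genes (calls in each comparison and their overlaps) stayed within 1.5 times under median-of-ratios or upper-quartile factors, no or a stricter low-count filter, DESeq2, limma-voom, and with Gm42418 or near-identical rows left out, the last 2 being alternatives added after the data were seen, as was thinning. With library totals in place of composition factors, genes higher with JQ1 numbered 1619 at 2 h (against 2947) and 2139 at 48 h (against 3645), genes lower at 2 h 4768 (against 3134), and genes higher at both 2 and 8 h 600 (against 996) and at both 8 and 48 h 348 (against 665). These factors shift the median log2 fold change of all genes by -0.27 (JQ1, 2 h), -0.33 (JQ1, 48 h), -0.18 (0 to 2 h) and -0.13 (0 to 48 h), and by 0.22 and -0.28 for the differences between 2 and 8 h and between 8 and 48 h. Upper-quartile factors shift it by 0.19 (JQ1, 48 h), -0.16 (0 to 48 h), and 0.22 and 0.22 for the differences between 8 and 48 h and between 2 and 48 h. Named genes that changed sign with library totals, with a call in at least 1 of the fits, were Irf4 at 2 h (-0.27), Pax5 at 48 h (-0.29) and Bach2 at 48 h (-0.024). Changes of sign without a call in either fit were not listed. A fit of the groups compared alone gave 1893 genes higher at 8 h (against 1249) and 1009 raised and lower at 8 h (against 627), and the cause was not tested. Thinning with Gm42418 left out gave 435 genes lower at both 8 and 48 h (against 716), with fewer counts and genes tested. Leaving out each library in turn, with fewer samples, moved the 8 h counts: 819 to 1110 higher (against 1249), 827 to 1155 lower (against 1314), 551 to 791 lower at 2 and 8 h (against 840), 460 to 807 lower and 424 to 803 higher at 8 and 48 h, and 413 to 565 raised and lower at 8 h, the lowest of each without JQ1 8 h replicate 1. Of 673 values of named genes 13 lost and 9 gained a call with library totals. Calls lost were 19 when thinned with Gm42418 left out, 10 without the low-count filter, 9 in DESeq2, 9 with the groups compared alone, 6 in limma-voom, 6 with upper-quartile factors and at most 10 with a library left out (JQ1 8 h replicate 1). Among 234 list tests 56 calls were lost with an estimated correlation, and only the lists called could lose one. With JQ1 at 2, 8 and 48 h, 9, 13 and 10 lists were called, and 3, 8 and 5 kept the call. Against 0 h at these times 10, 13 and 12 were called, and 6, 8 and 3 kept it. For the differences between 2 and 8, 8 and 48, and 2 and 48 h, 10, 13 and 9 were called. Of these 4, 2 and 4 kept the call.

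Replicate numbers did not pair the samples: correlations of same-numbered libraries' deviations ran from -0.16 to 0.20, 4 of 18 above 0.1, with the own number best in 8. With the replicate number as a block, 2894 genes were higher with JQ1 at 2 h, all 22 counts stayed within 1.5 times, and 4 gene calls and 1 list call were lost. Depth limits low genes most in the JQ1 48 h libraries, where 3 counts, the limit that a count of 0 allows, are up to 0.839 CPM, for counting error only.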

Other observations

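The gene groups in this part, 7 in all, and their tests were chosen after the data were seen, and counts are of genes past the threshold in edgeR's quasi-likelihood test. Aminoacyl tRNA synthetases, which charge tRNAs for protein synthesis, rose from 0 h and were lower with JQ1 at each time. At 8 h 16 of 18 were above 0 h. Lower with JQ1 at 2, 8 and 48 h were 15, 12 and 18 of 18 (median log2 fold change -0.44, -0.40 and -0.92), with the same direction under 3 other scalings. Proteasome subunits, which degrade tagged proteins, were above 0 h at 48 h in 35 of 37 and lower with JQ1 at 48 h in 36 (median -0.86). With JQ1 at 8 h 1 was lower. At 2 h 7 were lower and 2 higher with JQ1, which became 23 and 1 with library totals, 10 and 2 with upper-quartile factors and 6 and 3 with median-of-ratios factors. Of 82 ribosomal protein genes 79 were above 0 h at 48 h and 69 lower with JQ1 (median -0.57, and 55 lower and 2 higher with upper-quartile factors). At 2 h 3 were above and 22 below 0 h, with 61 below under library totals and 54 under upper-quartile factors. With JQ1 at 2 h 20 were higher and 1 lower, which became 36 and 1 with median-of-ratios factors and 0 and 3 with library totals. With JQ1 at 8 h 7 of them were higher and 1 lower. All 9 MHC class II genes, which present antigen, were below 0 h at 8 and 48 h, and with JQ1 6 were lower at 8 h, 3 lower at 2 h and 5 higher at 48 h (median 0.33, which turns to -0.010 with library totals). Kruppel-like factor genes, transcription factors that include regulators of quiescence, were higher with JQ1 at 2 h in 8 of 11 and lower in 1 (median 0.92). Of 5 immunoglobulin heavy chain constant genes 3 were lower and 1 higher with JQ1 at 48 h, and 1 was lower and 2 higher at 8 h.

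Histone genes with symbols starting Hist changed from 0 h and with JQ1. These comparisons share the untreated libraries, so their signs are not set against each other. Of 60 measured, 39 were below 0 h at 2 h and 41 at 8 h with none above, at 48 h 42 were above and 6 below 0 h, and with JQ1 40 were higher at 2 h (median 1.52), 18 higher at 8 h, and 24 lower and 4 higher at 48 h, with medians of the same sign under 3 other scalings. Of the 55 histone genes without a near-identical row 63.6% rose with JQ1 at 2 h as well. Near-identical rows were found by matching counts at a mean of at least 20. Low-count rows and genes that share part of their reads escape that check, so shared reads stay open as a cause. More cells in S phase with JQ1 at 2 h could raise histone transcripts, but the fixed G1/S list decided nothing, with a median of 0.061 and 7 members higher and 7 lower of 30, so this cannot be told apart from a direct effect of JQ1. Most histone transcripts lack a poly(A) tail, so a change in the share that carries one, which 3' libraries would read as a change in level, stays open and was not tested.

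Across the 13904 genes, the log2 fold changes with JQ1 at 2 and 8 h correlated with r = 0.58 (rho = 0.59), those at 8 and 48 h with r = 0.38 (rho = 0.31) and those at 2 and 48 h with r = 0.33 (rho = 0.32), genes not being independent replicates. The root mean square log2 difference per gene between group means, less the part from spread within groups, was 0.863 between the JQ1 and untreated 48 h groups, 0.905 between the JQ1 48 h and untreated 8 h groups and 0.941 between the JQ1 48 h and 0 h groups. The ratio of the distance to untreated 8 h to that to untreated 48 h was 1.05 and ran from 0.973 to 1.14 when each of 9 libraries was left out, so which of these groups lay closer was not decided. The JQ1 48 h group lay nearest to the JQ1 8 h group, at 0.730. Between the JQ1 and untreated groups the same distance was 0.718 at 2 h and 0.449 at 8 h.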
